A study of Mus musculus with 9 samples.

How the data were processed

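RNA from mouse knee joints was sequenced in 9 libraries, 3 for each of 3 groups. The groups were joints without surgery (Non surgery), joints given a lentivirus expressing Luc after anterior cruciate ligament transection (Luc), and joints given a lentivirus expressing PC2 after the same operation (PC2). Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with the NEBNext Ultra RNA kit, and the RNA of each group was mixed and sequenced as 3 technical repeats. Each group was therefore 1 pool of RNA, and the spread between its libraries, against which every p-value below was set, was technical and held no difference between mice. The number of mice per pool was not given in the sources used here.

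The deposited values were raw read counts per Ensembl gene ID, 1 table per library with 53379 gene IDs and 5 summary lines of HTSeq. HISAT2, HTSeq, DESeq2 and the mm10 build were named in the submitters' processing notes without versions. The annotation release, the strand setting of the counting and any read filter were not given in the sources used here. The summary lines stayed out of library sizes and tests. Reads outside annotated genes made up 7.33% ± 0.04 (SD, n = 3) in Non surgery, 9.08% ± 0.18 in Luc and 8.11% ± 0.06 in PC2 libraries, and reads that HTSeq could not assign to a single gene 6.52% ± 0.12, 5.81% ± 0.15 and 6.02% ± 0.08. The lines for reads not aligned, not unique or of low quality held 0 in all 9 tables. Symbols, coordinates, exon lengths and GC content came from GENCODE M21 (GRCm38, the mm10 build), which held 53274 of the gene IDs; 105 had no entry there. Where several IDs shared a symbol, the symbol stayed with the most abundant ID, and 80 IDs kept only their ID.

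HTSeq leaves reads in overlapping exons unassigned unless strand separates the genes, so overlapping genes can be undercounted. Tnnc2 had 2 to 8 counts and Tagln 3 to 12 counts per library, with 74% and 67.9% of their exon bases shared with Ube2c and Gm48529. Neither gene was tested, and both examples were chosen after their values were seen. Whether overlap alone left their counts so low was not examined. Values of near-identical paralogs (the Ear, Hba, Hbb and Serpina1 families) are uncertain for the same kind of reason.

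Library totals over genes lay between 17835989 and 19004316 counts. Pairs of libraries of 1 group were compared by a chi-square test over genes with at least 20 counts in sum. The statistic per degree of freedom was 3.94 to 8.67 within groups, above counting noise, so no library was a second copy of another.

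Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited. All 9 libraries entered 1 quasi-likelihood fit with a group factor, TMM factors and the filterByExpr filter (minimum count 10), which kept 17478 genes. The 3 contrasts were two-sided, and p-values were adjusted with the Benjamini-Hochberg method over all genes tested. A gene rose or fell where its adjusted p was under 0.05. A count of changed genes also asked for a fold change of at least 2, because p-values set against technical spread call small differences. Standard errors were computed as the size of the log2 fold change over the square root of the F statistic. CPM values are edgeR cpm() values on TMM-scaled library sizes, given as mean ± SD over 3 libraries.

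A set of 35 gene lists for tissues, cell types and pathways that a knee joint sample can hold was written from general knowledge before the data were examined, as were the tests, the rule for named genes and the alternatives. Each list was tested with camera (limma 3.58.1) on log-CPM with a preset correlation of 0.01, adjusted over the 35 lists within a comparison. The same test was run with a correlation estimated per list. For each list the members that rose, fell or did not pass were counted, with p-values adjusted over all genes and adjusted over the list alone.

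The genes named are the 10 largest rises and 10 largest falls per comparison among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and libraries that did not overlap; up to 4 members per list with the largest change among those that passed; 11 genes fixed by name; and 5 genes per direction of the overlap between comparisons. Gene models without a given name, immunoglobulin and T cell receptor segments and pseudogenes were left out. Some genes that this rule chose are not reported here. Where another gene is named, the text says that it was chosen after its values were seen.

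The fit was tested on simulated counts for the PC2 against Luc comparison with 17239 genes. At an adjusted p under 0.05 it recovered 87.8% of genes changed 1.5-fold, 92% of those changed 2-fold, 100% of those changed 4-fold and 98% of those changed 8-fold. With the 2-fold limit it recovered 58% of genes simulated exactly at 2-fold, and 5 unchanged genes were called. A simulated 1.5-fold shift of the endothelial list was recovered, and 0 of the 34 other lists were called. Genes were drawn independently, so this simulation cannot show how often the list test calls lists whose members vary together.

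The alternatives were median-of-ratios size factors, library size only, TMM factors without muscle, blood and mitochondrial genes, other filters on low counts, DESeq2 1.42.0, limma-voom, a test against a fold of 2 (glmTreat), no size limit, only the 6 libraries compared, an offset for GC content and gene length (mgcv 1.9.3), the replicate number as a block, the list test fry, and leaving out each library. GC content and length were known for 99.9% of the tested genes. Python 3.11.15 was used for the gene tables and plots.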

Results

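Gene expression was measured by RNA sequencing in whole knee joints of male C57BL/6 mice. The study addressed a surgical model of osteoarthritis, in which cutting the anterior cruciate ligament (ACLT) destabilises the joint, and a virus expressing PC2 given into the operated joint. ACLT was done at 8 weeks of age, virus went into the joint 1 week later, and joints were collected 8 weeks after that. There were 3 libraries from unoperated joints (Non surgery), 3 from operated joints with the control virus expressing Luc, and 3 from operated joints with the virus expressing PC2. Each library held 17835989 to 19004316 counts in genes. Because the 3 libraries of a group came from 1 mixture of RNA, p-values measure only technical spread and say nothing of differences between mice. In a principal component analysis, the first component (65.1% of variance) separated Non surgery from the other libraries and the second (15.3%) separated Luc from PC2 libraries.

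The first comparison asked how operated joints with the control virus differed from unoperated joints. Transcripts of cartilage, bone, connective tissue matrix and inflammation were higher in Luc than in Non surgery libraries, and those of skeletal muscle were lower. The groups differ by the operation, by the injection of virus and by pool, and the age of the Non surgery mice was not given in the sources used here, so no single cause can be assigned. Col2a1, the main fibrillar collagen of cartilage (chromosome 15, 97975602 to 98004695), rose 10.3-fold from 220.1 ± 17.3 to 2272 ± 38.7 CPM (SD, n = 3). Fosb, an immediate-early transcription factor, rose 253-fold from 2.17 ± 0.341 to 551.4 ± 28.5 CPM, and the neutrophil-attracting chemokines Cxcl1 and Cxcl2 rose 52.5-fold and 38.6-fold. Myh7, the myosin heavy chain of slow muscle fibres, fell 35.8-fold from 96.21 ± 8.87 to 2.68 ± 0.372 CPM. Of 17478 genes tested, 10279 passed an adjusted p of 0.05, and 2752 of these differed at least 2-fold, 1648 higher and 1104 lower. In 10991 genes the libraries of the 2 groups did not overlap, against 1748 for exchangeable libraries, which technical repeats of the same pool are not. Scaling by library size only moved the median of all genes from 0.025 to 0.185 on the log2 scale and the split of calls from 1648 higher and 1104 lower to 2065 higher and 824 lower, so fold changes here are relative to the TMM scale.

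Of 22 cartilage matrix and chondrocyte genes, 20 rose and 2 fell, with a median log2 fold change of 2.07. Col9a1 rose by 4.08 ± 0.06 (SE), Col2a1 by 3.37 ± 0.043, Epyc by 3.21 and Matn4 by 3.14. Acan, the core protein of the main cartilage proteoglycan, rose 2.52-fold and Sox9, the chondrocyte transcription factor, 3.57-fold. Sox6 and Matn1 fell (chosen after their values were seen). Of 11 hypertrophic chondrocyte genes, 9 rose and 1 fell (9 and 2 when adjusted over the list alone), among them Col10a1, the collagen of hypertrophic cartilage, up 7.98-fold and Panx3 up 6.2-fold. Of 15 osteoblast and osteocyte genes, 13 rose and 1 fell, led by Smpd3 (2.02), Alpl (2.01), the alkaline phosphatase of mineralising bone, and Sost (1.93), an osteocyte inhibitor of Wnt signalling. Of 14 osteoclast genes, 11 rose and 3 fell, with Ctsk, the collagen-cleaving cathepsin of osteoclasts, at 1.83. These 4 lists were called higher by camera, also with an estimated correlation (adjusted p = 0.0161, 0.0415, 0.0415 and 0.0424 in this order). The fast muscle list moved the other way in the same libraries, with a median of -1.22. A smaller share of muscle in the Luc pool would also raise the genes of other tissues, and this was not tested here.

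Genes of extracellular matrix and its turnover were higher as well. Of 22 fibrillar collagen and fibrosis genes, 21 rose and 1 fell, with Col3a1 at 2.96, the collagen-crosslinking Loxl2 at 2.72 and Col6a1 at 2.54. The median was 1.88, and the list's call was lost with an estimated correlation (adjusted p = 0.0605 with an estimated correlation). Of 19 matrix-degrading proteases, 16 rose and 2 fell, including Mmp3 (4.22), the aggrecanase Adamts4 (3.27) and the collagenase Mmp13 (2.29, 4.87-fold). Adamts5, another aggrecanase, rose 1.61-fold. Of 17 synovial and other fibroblast genes, 15 rose and 2 fell, with the hyaluronan synthase Has1 at 3.42 and the lubricin gene Prg4 at 1.45. Vcam1, an adhesion molecule of lining fibroblasts, had -1.42 (chosen after its values were seen). All 8 tenocyte genes rose, with a median of 1.95. Their largest rise was in Egr1 (4.82), which is also an immediate-early gene, followed by Tnmd (2.16) and Kera (2.12).

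Inflammatory and stress genes rose together with the matrix genes. Of 24 cytokines and chemokines, 16 rose and 4 fell, with a median of 1.51. Besides Cxcl1 and Cxcl2, Ptgs2, the inducible cyclooxygenase, rose by 4.72 and Ccl8 by 3.39, while Il1b rose 4.05-fold and Il6 6.87-fold. Of 16 immediate-early and heat-shock genes, 12 rose and 3 fell, led by Fosb (7.99), Fos (5.24), Egr1 (4.82) and Junb (2.94). A difference in handling before the RNA was preserved could also change immediate-early genes and rapidly induced cytokine genes. This was not tested for Luc against Non surgery. The senescence and secretory list had 16 of 20 members higher and 3 lower. Its largest rises were those of the secreted products Cxcl1, Mmp3, Il6 and Ccl2 (2.41). Of the cell cycle inhibitors in it, Cdkn2a rose 4.72-fold from 0.257 ± 0.0376 CPM, and Cdkn1a fell 2.06-fold from 218.2 ± 4.54 to 105.9 ± 2.77 CPM. Of 24 interferon-stimulated genes, 16 rose and 3 fell, with Zbp1 at 1.19 (adjusted p = 0.134 with an estimated correlation). Of 16 complement genes, 9 rose and 2 fell, with C1s1 at 1.24 (adjusted p = 0.0966 with an estimated correlation).

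Muscle and mitochondrial transcripts were lower in Luc libraries. All 18 fast muscle genes fell, with a median of -1.22, led by Myh1 (-2.13) and the giant sarcomere proteins Neb (-1.76) and Ttn (-1.74). All 11 slow and oxidative muscle genes fell, with a median of -3.23, led by Myh7 (-5.16), Myh2 (-3.70), Tnnc1 (-3.66) and Myl3 (-3.64). Of 13 genes of muscle regeneration and denervation, 9 fell and 2 rose (10 and 2 when adjusted over the list alone), with the neuromuscular junction kinase Musk at -3.60. Of 38 nuclear genes of oxidative phosphorylation, 37 fell and 0 rose (38 and 0 when adjusted over the list alone), with the muscle isoforms Cox8b, Cox6a2 and Cox7a1 at -1.49, -1.47 and -1.46 (adjusted p = 0.0616 with an estimated correlation). Of 15 mitochondrial-encoded genes, 9 fell and 6 did not pass (adjusted p = 0.276 with an estimated correlation). All genes with a mitochondrial (mt-) symbol, tested or not, took 9.93% ± 0.92 of counts in Non surgery and 5.33% ± 0.42 in Luc libraries (SD, n = 3). Among the 10 largest falls were also Ppp1r3c (-3.65), a glycogen-targeting phosphatase subunit, and Ppara (-3.58), a regulator of fatty acid oxidation.

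Blood and marrow lists moved apart. All 10 megakaryocyte genes fell, with a median of -1.60. Of 15 erythroid genes, 14 fell and 0 rose, with a median of -0.74, and of 16 neutrophil genes 15 fell and 1 rose, with Chil3 at -1.44 (adjusted p = 0.0623 with an estimated correlation). Of 15 B cell genes, 12 rose and 2 fell (12 and 3 when adjusted over the list alone). Those that rose most belong to B cell precursors, namely Igll1 (4.19, 18.2-fold), Vpreb1 (3.92), the recombinase gene Rag1 (3.74) and Dntt (2.71), while Ighm (chosen after its values were seen) fell. Macrophage genes went both ways (9 rose, 4 fell, 3 did not pass), with Timd4 at -2.28 and Cd163 at -1.79; their median was 0.19 and their mean -0.08. Of 75 cytosolic ribosomal proteins, 33 rose and 0 fell (31 and 0 when adjusted over the list alone), with a median of 0.14 (adjusted p = 0.597 with an estimated correlation). Of 22 cell cycle genes, 14 fell and 7 rose (adjusted p = 0.0978 with an estimated correlation).

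In this comparison camera called 24 of the 35 lists, 15 higher and 9 lower, and 16 of the calls held with an estimated correlation. The lists not called were those of Polycomb, macrophage, T and NK cell, mast cell and eosinophil, adipocyte, endothelial, smooth muscle, Schwann cell, keratinocyte, ribosome biogenesis and unfolded protein response genes. In 27 lists the counts were the same when adjusted over the list alone. Leaving out Non surgery replicate 1 or Luc replicate 2 ended the call of the ribosomal proteins (adjusted p = 0.0751 and 0.0603), and leaving out Non surgery replicate 3 or any of Luc replicates 1, 2 and 3 ended that of the cell cycle (0.0512, 0.0546, 0.053 and 0.0521). Calls were gained by the Polycomb list without Non surgery replicate 1 or Luc replicate 2 (0.049 and 0.0474), by ribosome biogenesis without Non surgery replicate 1 or Luc replicate 3 (0.0262 and 0.0354), and by the endothelial list without Non surgery replicate 2 (0.0488).

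**Figure D1:**
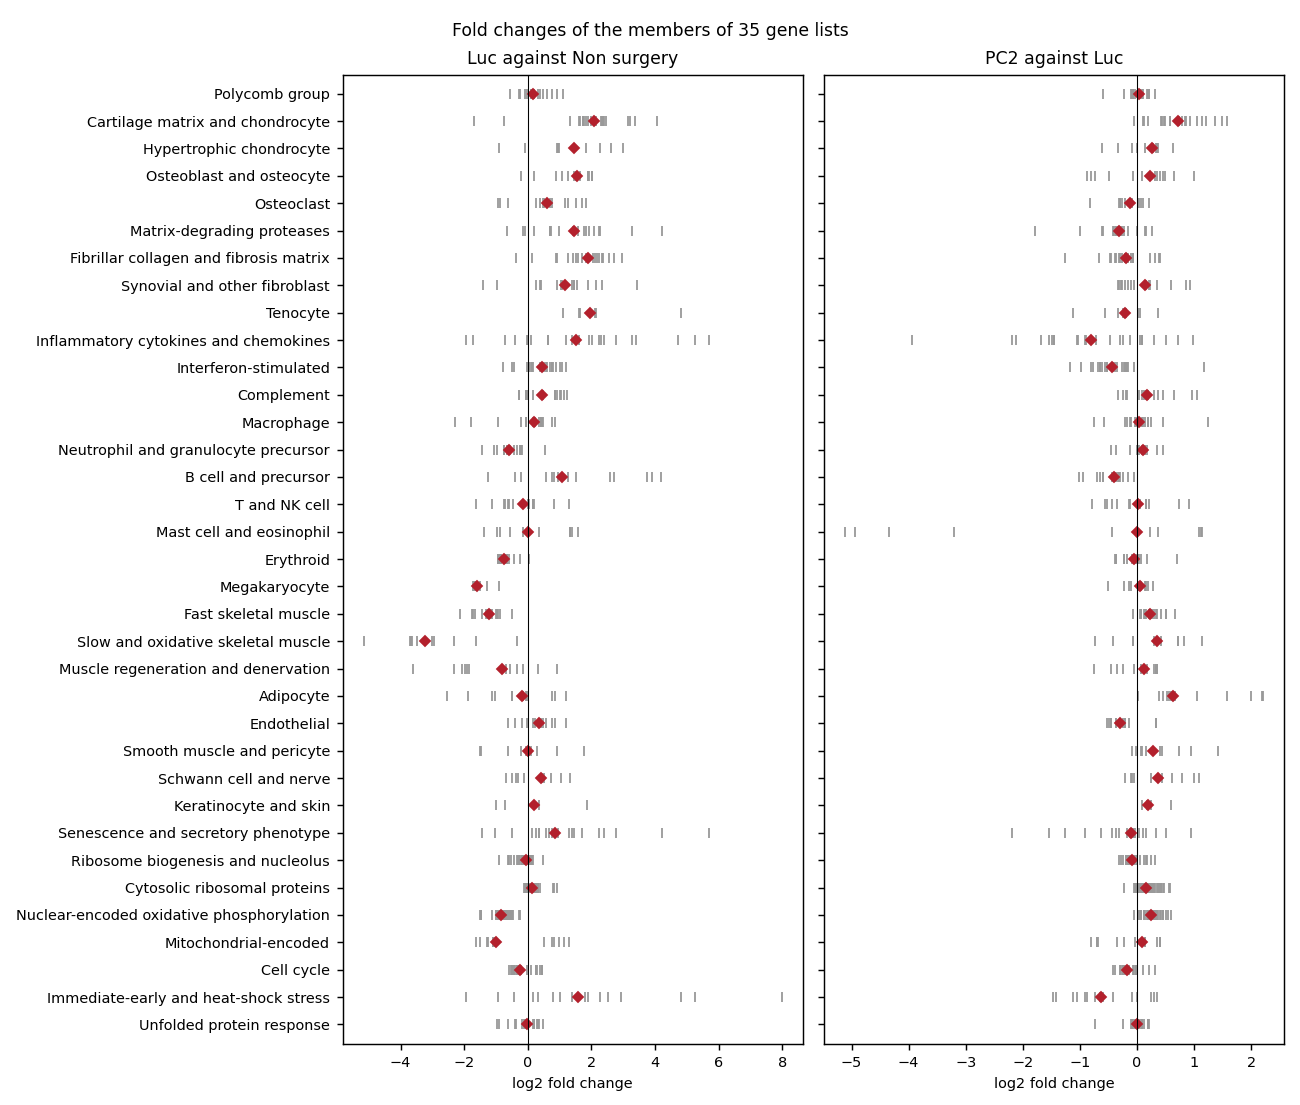
Log2 fold changes of the members of 35 gene lists (grey ticks, 1 per gene) and their medians (red diamonds), for Luc against Non surgery on the left and PC2 against Luc on the right; the 2 x axes differ in range. The cartilage list has a median of 2.07 on the left and 0.72 on the right, and the cytokine list 1.51 and -0.80.

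The second comparison asked what the PC2 virus changed in operated joints. Cartilage matrix and fat genes were higher in PC2 than in Luc libraries, and cytokine, immediate-early and interferon-stimulated genes were lower. Col2a1 rose 1.72-fold from 2272 ± 38.7 to 3914 ± 26.5 CPM (SD, n = 3) and Col9a1 2.99-fold from 57.35 ± 1.77 to 171.2 ± 1.43 CPM. Cxcl2 fell 15.4-fold from 42.9 ± 2.04 to 2.78 ± 0.553 CPM, and Epx, the peroxidase of eosinophil granules (chromosome 11, 87864000 to 87875536), fell 34.5-fold from 287.6 ± 1.28 to 8.33 ± 0.296 CPM. The largest rise among the named genes was 10.8-fold, in the lipid droplet gene Pnpla3. In all, 6058 genes passed an adjusted p of 0.05 and 578 of them differed at least 2-fold, 228 higher and 350 lower. The libraries of the 2 groups did not overlap in 8394 genes, against 1748 for exchangeable libraries, which repeats of 1 pool per group are not.

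Of 22 cartilage matrix and chondrocyte genes, 19 rose and 0 fell, 6 of them at least 2-fold, with a median of 0.72 (adjusted p = 0.0158 with an estimated correlation). Col9a1 rose by 1.58 ± 0.04 (SE), Col9a3 by 1.49, Ucma by 1.36 and Col9a2 by 1.21. Acan rose 1.38-fold. Sox9 rose 1.14-fold (adjusted p = 0.0108), a call that ended without Luc replicate 3 (adjusted p = 0.0535). Of 11 hypertrophic chondrocyte genes, 7 rose and 2 fell, and camera did not call the list (adjusted p = 0.18). Its largest changes were those of Ihh (0.62), a signal of prehypertrophic chondrocytes, and of Spp1 (-0.62), while Col10a1 rose 1.21-fold. Of 15 osteoblast and osteocyte genes, 9 rose and 4 fell (9 and 5 when adjusted over the list alone), and the list was not called (adjusted p = 0.116). The falls were in the osteocyte genes Sost (-0.88), Mepe (-0.80) and Dmp1 (-0.73) and in Phex (chosen after its values were seen), and the largest rise was in Car12 (2-fold). Muscle genes were slightly higher in the same libraries. In the fast muscle list 15 of 18 rose and 1 fell (17 and 1 when adjusted over the list alone), with a median of 0.23 (adjusted p = 0.0931 with an estimated correlation). In the slow list 7 of 11 rose and 2 fell, with Myh2 at 1.13 (adjusted p = 0.109 with an estimated correlation).

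Fat genes were higher in the PC2 libraries. Of 13 adipocyte genes, 12 rose and 0 fell, with a median of 0.63 (adjusted p = 0.0228 with an estimated correlation). Scd1, a desaturase of fatty acid synthesis, rose 4.65-fold from 217.1 ± 8.02 to 1009 ± 7.26 CPM, the leptin gene Lep 4.56-fold, Retn 3.99-fold and the lipid droplet gene Plin1 2.99-fold. Of 11 Schwann cell and nerve genes, 6 rose and 1 fell, with the myelin gene Ncmap up 2.11-fold (adjusted p = 0.113 with an estimated correlation). In the smooth muscle list 6 of 10 rose and 0 fell, with Cnn1 at 1.42 (adjusted p = 0.109 with an estimated correlation), and in the complement list 9 of 16 rose and 3 fell (9 and 4 when adjusted over the list alone), with Cfd, which fat cells also express, at 1.05 (adjusted p = 0.109 with an estimated correlation).

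Inflammatory genes were lower in the PC2 libraries. Of 24 cytokines and chemokines, 15 fell and 2 rose (15 and 3 when adjusted over the list alone), with a median of -0.80 (adjusted p = 0.0393 with an estimated correlation). Cxcl2 fell by 3.94 ± 0.102 (SE), Il6 by 2.19 ± 0.22, Ptgs2 by 2.11 and Ccl8 by 1.68, and Il1b fell 2.07-fold to 31.78 ± 0.71 CPM. The chemokines Ccl3 and Ccl4 rose (chosen after their values were seen). Of 16 immediate-early and heat-shock genes, 11 fell and 2 rose, with a median of -0.64 (adjusted p = 0.0446 with an estimated correlation). Atf3 (-1.46), Fosb (-1.41), Egr1 (-1.12) and Fos (-1.05) fell, and the rises were in the heat-shock genes Hspb1 and Hsph1 (chosen after their values were seen). Of 24 interferon-stimulated genes, 19 fell and 1 rose (20 and 1 when adjusted over the list alone), with a median of -0.44 (adjusted p = 0.0408 with an estimated correlation). Zbp1 fell by 1.18, Ifit1 by 0.97 and Oasl2 by 0.80, and Ifi27l2a rose by 1.18.

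Among 19 matrix-degrading proteases 14 fell and 2 rose, with a median of -0.31 (adjusted p = 0.0517 with an estimated correlation). Mmp12, the macrophage elastase, fell by 1.79, Adamts1 by 0.99 and Adamts4 by 0.61, and Mmp13 fell 1.26-fold to 956.2 ± 11.5 CPM. Adamts5 was 1.1-fold higher (adjusted p = 0.0326), a call that ended without Luc replicate 1, PC2 replicate 1 or PC2 replicate 3 (adjusted p = 0.126, 0.0953 and 0.11). Prg4 rose 1.1-fold. Of 22 fibrillar collagen and fibrosis genes, 15 fell and 4 rose (17 and 4 when adjusted over the list alone), with the microfibril gene Fbn1 at -0.67 (adjusted p = 0.327 with an estimated correlation).

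The senescence and secretory list had 9 of 20 members lower and 2 higher (9 and 3 when adjusted over the list alone), with a median of -0.11 (adjusted p = 0.109 with an estimated correlation). Il6 and Cxcl1 (-1.55), the members with the largest falls, encode secreted proteins, and Gdf15 rose by 0.95. The cell cycle inhibitors did not pass: Cdkn1a had a log2 fold change of 0.027 ± 0.037 (SE, adjusted p = 0.623) and Cdkn2a -0.63 ± 0.33 (adjusted p = 0.155), the latter at 1.23 ± 0.206 CPM in Luc and 0.798 ± 0.402 in PC2 libraries. Without PC2 replicate 1, Cdkn2a passed at -1.11 (adjusted p = 0.0263). Of 32 ribosome biogenesis and nucleolar genes, 11 fell, 3 rose and 18 did not pass, with a median of -0.09. The largest falls were in Utp20 (-0.32) and Heatr1 (-0.28), and Nop10 rose by 0.32, a call that ended without Luc replicate 1 or PC2 replicate 2 (adjusted p = 0.105 and 0.0706). The call of this list ended with an estimated correlation (adjusted p = 0.156 with an estimated correlation), with median-of-ratios factors (0.0593) and without Luc replicate 3 or PC2 replicate 1, 2 or 3 (0.108, 0.0862, 0.051 and 0.0501). Of 75 cytosolic ribosomal proteins, 37 rose and 0 fell (38 and 0 when adjusted over the list alone), with a median of 0.16 (adjusted p = 0.388 with an estimated correlation).

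Blood cell genes differed by cell type. The 11 mast cell and eosinophil genes went both ways: 5 fell, among them the eosinophil granule genes Epx (-5.11), Ear1 (-4.95), Prg2 (-4.34) and Ear2 (-3.21), and 4 rose. The list's median was 0.01 and its mean -1.28, and camera did not call it (adjusted p = 0.0686), except without Luc replicate 2 (0.0418) or PC2 replicate 1 (0.0401). Ear1 and Ear2 belong to a family with near-identical copies, so their values are uncertain. In the B cell list 14 of 15 fell and 0 rose, with a median of -0.41 (adjusted p = 0.0393 with an estimated correlation), led by Dntt (-1.02), Rag1 (-0.94) and Igll1 (-0.70). In the endothelial list 11 of 13 fell and 2 rose, with Ptprb at -0.53 and Kdr, a VEGF receptor, at -0.48 (adjusted p = 0.0408 with an estimated correlation). In the cell cycle list 13 of 22 fell and 3 rose, with Cenpf at -0.43 and Mki67 at -0.39 (adjusted p = 0.0408 with an estimated correlation). Camera called neither the neutrophil list (9 rose, 3 fell, median 0.10; called without Luc replicate 2, adjusted p = 0.0486) nor the macrophage list (4 rose, 5 fell, median 0.03; 6 and 6 when adjusted over the list alone). Of 38 nuclear genes of oxidative phosphorylation, 29 rose and 0 fell (30 and 0 when adjusted over the list alone), with Cox8b at 0.59 (adjusted p = 0.16 with an estimated correlation).

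Camera called 19 of the 35 lists in PC2 against Luc, 9 higher and 10 lower, and 8 of the calls held with an estimated correlation. Among lists not called were those of osteoclast, tenocyte, fibroblast, T and NK cell, erythroid, megakaryocyte, muscle regeneration, keratinocyte, mitochondrial-encoded and unfolded protein response genes. Of 20 Polycomb group genes, 2 rose, 2 fell and 16 did not pass (1 and 2 when adjusted over the list alone), with Phc3 at -0.60 and Ring1 at 0.32, and this list was not called either (adjusted p = 0.73). The mitochondrial-encoded list was called higher without Luc replicate 1 (adjusted p = 0.0179). In 21 lists the counts were the same when adjusted over the list alone.

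**Figure D2:**
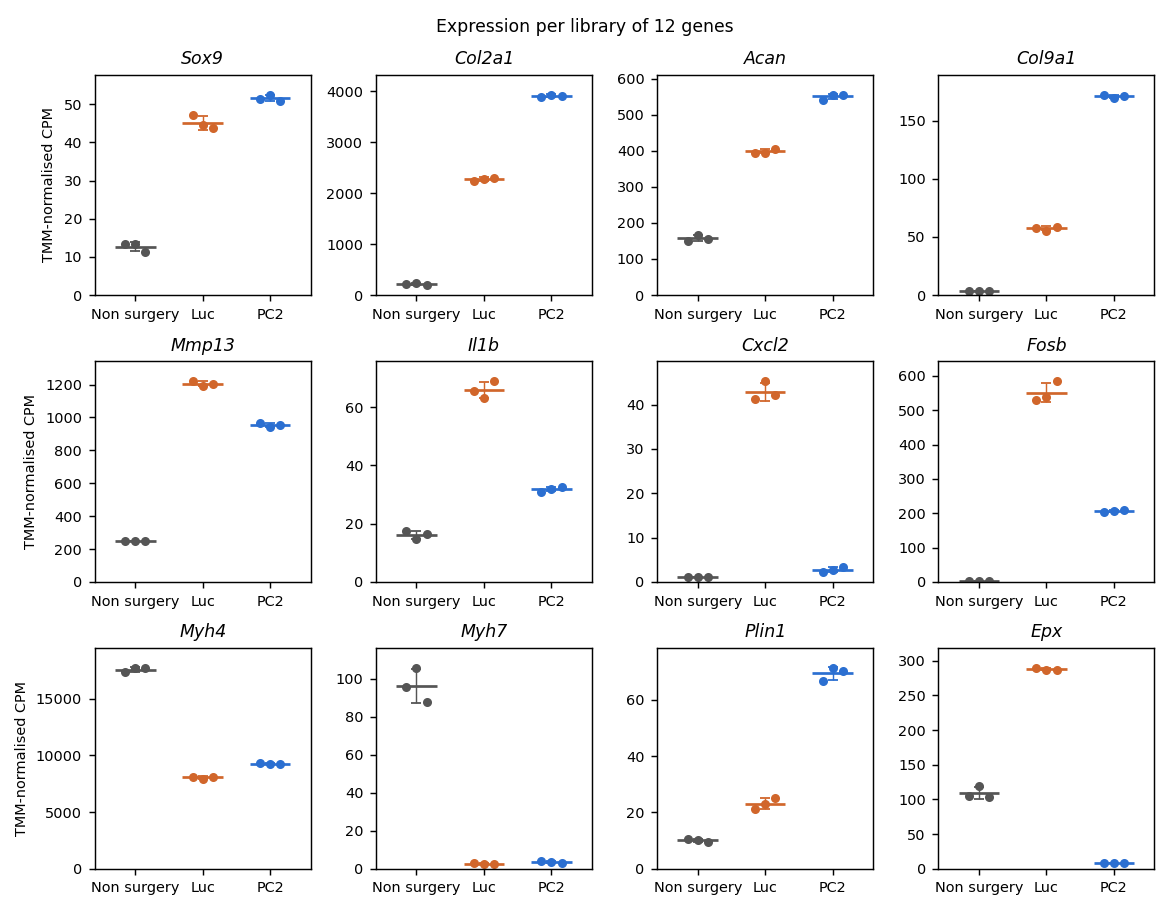
TMM-normalised CPM of 12 genes in each of the 9 libraries (points), with the mean of each group (horizontal line) and its SD (error bar, n = 3); each panel has its own y axis from 0. Col2a1 lies at 220.1, 2272 and 3914 CPM in Non surgery, Luc and PC2 libraries, and Epx at 109.4, 287.6 and 8.33 CPM.

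The third comparison asked how far PC2 libraries stood from unoperated joints. Cartilage and bone genes were higher and slow muscle genes lower, as in Luc libraries. Col9a1 rose 50.4-fold from 3.39 ± 0.229 to 171.2 ± 1.43 CPM (SD, n = 3), Col2a1 17.8-fold and Fosb 95.3-fold. Pdk4, a kinase that limits glucose oxidation, fell 46.4-fold from 2253 ± 37 to 48.54 ± 2.28 CPM, Myh7 26.9-fold, and Ucp3, an uncoupling protein of muscle mitochondria, 25.2-fold. In total 10952 genes passed an adjusted p of 0.05 and 2860 of them differed at least 2-fold, 1718 higher and 1142 lower. With library size only, the median of all genes was 0.168 in place of 0.010 and the split 2122 higher and 834 lower. The libraries did not overlap in 11530 genes, against 1748 for exchangeable libraries, which repeats of 1 pool per group are not.

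Of the 22 cartilage genes, 20 rose and 2 fell in PC2 against Non surgery, with a median of 2.79. The osteoblast list had 14 of 15 members higher and 0 lower, and the fibrosis list 20 of 22 higher and 1 lower (adjusted p = 0.0672 with an estimated correlation). Among the proteases 16 of 19 rose and 3 fell, with Mmp3 at 3.86 and Mmp13 at 1.95. All 18 fast muscle genes and all 11 slow muscle genes fell, with medians of -1.02 and -2.56. Of 24 cytokines and chemokines, 13 rose and 6 fell, with a median of 0.81 (adjusted p = 0.0672 with an estimated correlation). Il6 did not pass, at 0.59 ± 0.308 (SE, adjusted p = 0.106), except with library size only (adjusted p = 0.0412), and Il1b rose 1.96-fold. Of 24 interferon-stimulated genes 7 rose and 7 fell, and the list was not called (adjusted p = 0.759). Of the 11 mast cell and eosinophil genes, 8 fell and 3 rose, with Epx at -3.71 (adjusted p = 0.0611 with an estimated correlation). Complement genes rose in 13 of 16 cases and fell in 2, with Cfd at 1.92. The cytosolic ribosomal proteins rose in 62 of 75 cases and fell in 1 (64 and 1 when adjusted over the list alone; adjusted p = 0.316 with an estimated correlation). In the ribosome biogenesis list 16 of 32 fell and 3 rose (15 and 3 when adjusted over the list alone), with Rrp12 at -1.05 (adjusted p = 0.0672 with an estimated correlation and 0.0692 with library size only). Cdkn1a fell 2.02-fold and Cdkn2a rose 3.05-fold. Camera called 27 of the 35 lists, 16 higher and 11 lower, and 12 of the calls held with an estimated correlation.

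The last question was whether genes changed in Luc against Non surgery moved back in PC2 against Luc. Of genes changed at least 2-fold in both, 199 moved in opposite directions, 125 up then down and 74 down then up. Cxcl2 went from 1.1 ± 0.0305 CPM in Non surgery to 42.9 ± 2.04 in Luc and 2.78 ± 0.553 in PC2 libraries (SD, n = 3). Il6, Ptgs2, the protease-activated receptor gene F2rl1 and Olfr810 also rose and then fell. Among genes that fell and then rose were Eps8l1 (9.41 ± 0.99, 1.2 ± 0.0437 and 7.22 ± 0.672 CPM), Odf3l2, Lep, the muscle M-band gene Myom3 and the potassium channel gene Kcng4. In PC2 against Non surgery, F2rl1 (0.12, adjusted p = 0.59), Olfr810 (0.09, adjusted p = 0.758) and Il6 (0.59, adjusted p = 0.106) did not pass. Eps8l1 and Lep passed there, but Eps8l1 not with library size only (adjusted p = 0.101) and Lep not with DESeq2 (adjusted p = 0.0771). The call of Eps8l1 also ended without Non surgery replicate 1 or PC2 replicate 1 (adjusted p = 0.0558 and 0.0557). That of Lep ended without Non surgery replicate 2 or 3 or PC2 replicate 2 or 3 (adjusted p = 0.145, 0.0748, 0.0694 and 0.268). Another 22 genes rose in both comparisons and 26 fell in both.

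Both comparisons use the Luc libraries, which alone pushes their fold changes in opposite directions. Independent lists of these sizes would share 33 genes up then down, 14.4 down then up, 21.5 up in both and 22.1 down in both. In 30 simulations in which the 3 groups did not differ and the comparisons shared 3 libraries, the mean count was 0.13 in each opposite direction. No simulated gene was changed, so that count was bound to be small and sets no scale for the real one. Across genes, the covariance of the fold changes was -0.0863, against -0.0172 (SD 0.00066) in the simulations, a difference of -0.0691, and the correlation was -0.233 against -0.491. The 2 fold changes had opposite signs in 56.3% of genes, against 66.3% in the simulations. The simulations hold technical noise only: a deviation of the 1 Luc pool from other operated mice would give the same opposite moves and is not in them. Of the 1648 genes that rose in Luc, 1281 (77.7%) were also called higher in PC2 against Non surgery, and of the 1104 that fell 751 (68%) were also called lower. Those comparisons share the Non surgery pool, which alone favours such overlap, and no value without it was computed.

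**Figure D3:**
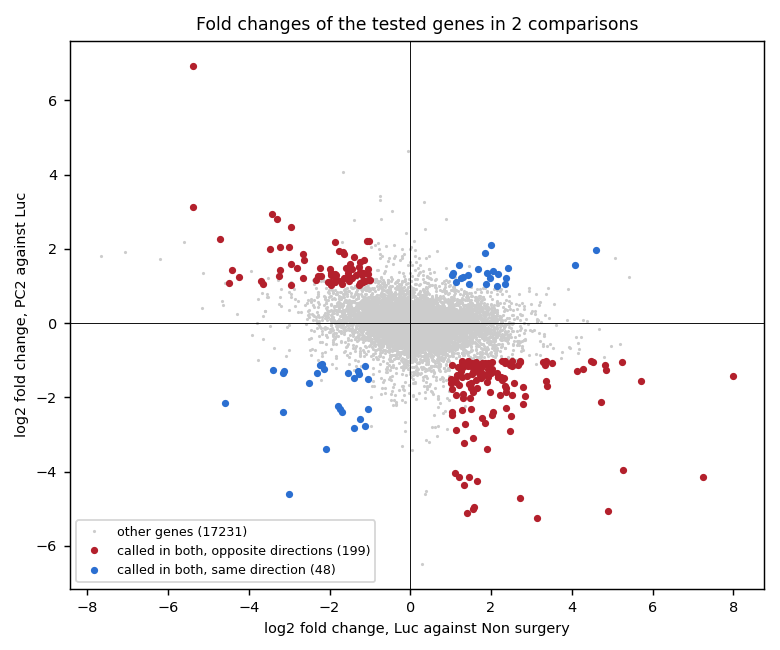
Log2 fold change of each of the 17478 tested genes in Luc against Non surgery (x axis) and in PC2 against Luc (y axis). Red points are the 199 genes called at least 2-fold in both comparisons in opposite directions, blue points the 48 called in both in the same direction, and grey points the other 17231 genes.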

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

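Reads outside annotated genes, which no comparison above used, made up more of the operated libraries. They took 9.08% ± 0.18 (SD, n = 3) of reads in Luc and 8.11% ± 0.06 in PC2 libraries, above the 7.33% ± 0.04 in Non surgery libraries. No explanation for this share was tested.

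Other splits of the same libraries were compared with the real groups, with bounds written after the counts were known. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each of the 3 comparisons 1 split, the real one, gave as large a count. The real splits gave 2752 genes in Luc against Non surgery, 578 in PC2 against Luc and 2860 in PC2 against Non surgery, and the highest other split gave 0 in each. For the gene lists called, the real splits gave 24, 19 and 27, and the highest other splits 18, 9 and 19. For the genes moved in opposite directions, 100 splits of the 9 libraries were drawn. The real one gave 199 genes, the highest other 50, and 1 of 100 splits, the real one, gave as many. Each group was 1 pool, so splits that mix pools put the difference between pools into the spread, and the real split had to come out highest. Whether chance can be excluded is therefore left open for this count.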

How the results depend on the processing

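The alternatives below were chosen before the data were examined. The test against a fold of 2 (glmTreat) gave 1537 genes in Luc against Non surgery, 142 in PC2 against Luc and 1559 in PC2 against Non surgery, and dropping the size limit gave 10279, 6058 and 10952 genes and 2707 moved in opposite directions; both change what is counted by construction. Under the 11 other alternatives the counts lay at 2388 to 3227, 436 to 740 and 2466 to 3386, and leaving out single libraries gave 2770 to 2813, 557 to 590 and 2834 to 2936. The opposite-direction count lay at 160 to 207 under 4 alternatives and at 193 to 212 without single libraries.

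With the replicate number as a replicate block the counts were 2744, 577, 2852 and 199. The numbers did not pair the libraries: 2 of 9 correlations between deviations of same-numbered libraries were above 0.1 (range -0.121 to 0.141). Of 105 list results the block changed 1, ending the call of the cell cycle in Luc against Non surgery (adjusted p = 0.0543).

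Of 105 list results, 34 lost their call with an estimated correlation, which holds technical co-variation only. The test fry, which asks another question, added a call in 24 list results. It also called the unfolded protein response list lower in PC2 against Non surgery (adjusted p = 0.0293). Camera gave that list the other direction without a call (adjusted p = 0.951). Its median was 0.063 and its mean -0.124, and the cause of the reversal was not tested. Among named genes, DESeq2 ended 11 calls, and leaving out single libraries ended the call of 22 gene and comparison pairs, 0 of them in Luc against Non surgery. Depth limits scarce genes such as Cdkn2a, near 1 CPM, more than abundant ones.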

Other observations

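The genes of lipid synthesis and fuel use given here were chosen after their values were seen, and no list of them was tested. Fasn, the fatty acid synthase, stood at 75.52 CPM in Non surgery, 94.25 in Luc and 248.6 in PC2 libraries, and rose 2.64-fold in PC2 against Luc. Thrsp, which fat-forming tissues express, rose 2.96-fold and Acaca 1.37-fold in the same comparison, while Acly (0.01, adjusted p = 0.808) and the elongase gene Elovl6 (0.145, adjusted p = 0.22) did not pass. Pdk4, which is high in fasted muscle, went from 2253 CPM to 253.3 and 48.54, Ucp3 from 350.6 to 33.35 and 13.92, and Angptl4 fell 2.24-fold in PC2 against Luc.

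Genes of the circadian clock, also chosen after their values were seen and not tested as a list, went different ways. Npas2 rose 8.77-fold and Nr1d1 5.08-fold in Luc against Non surgery, and Arntl 1.66-fold, Clock 1.6-fold and Dbp 1.51-fold, while Per2 fell 1.91-fold, Tef 1.84-fold, Per3 1.36-fold and Per1 1.34-fold, and Nr1d2 did not pass (-0.01, adjusted p = 0.915). In PC2 against Luc, Per1 fell 2.26-fold, Per2 1.41-fold, Nr1d2 1.31-fold, Clock 1.24-fold and Per3 and Dbp 1.22-fold, while Npas2 (adjusted p = 0.536), Nr1d1 (0.1), Arntl (0.0711) and Tef (0.312) did not pass. The hour of collection was not given in the sources used here. Zfp871 fell 7.43-fold in PC2 against Luc. Lcor, Lnpep, Cytl1 and Lars2 were chosen after their values were seen: Lcor and Lnpep fell 4.59-fold and 3.47-fold in the same comparison, and Cytl1, a secreted protein of cartilage, rose 3.52-fold. Lars2 varied widely between PC2 libraries, at 215.8 ± 118 CPM (SD, n = 3).

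The tests of the 3 patterns that follow were chosen after the results were seen. The first pattern is that 10 eosinophil genes, picked after their values were seen, all fell in PC2 against Luc, with a median of -4.19 on the log2 scale, after 8 of 10 had risen in Luc against Non surgery. A smaller share of marrow and blood in the PC2 pool would lower other marrow cells alike, but the lowest median among the neutrophil, erythroid and megakaryocyte lists was -0.057. The B cell list did fall, with a median of -0.41, far short of the eosinophil genes, so a smaller marrow share is argued against only as the whole cause. Reads shared between Ear paralogs do not account for it, since eosinophil genes outside that family had a median of -4.13. A difference between the mice that went into each pool stays open and cannot be told apart from an effect of the virus, because there was 1 pool of RNA per group; fewer eosinophils and less RNA per eosinophil stay open as well.

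The second pattern is the rise of cartilage matrix genes in PC2 against Luc, with 19 of 22 genes higher. A smaller share of muscle would raise every other tissue's genes and lower those of muscle, but the fast muscle list had a median of 0.23. With an offset for GC content and gene length the cartilage median was 0.69, against 0.72 without. More cartilage tissue in the PC2 pool and more matrix RNA per chondrocyte both predict that most of the list rises, so the 19 rises cannot tell them apart, and how joints were trimmed may differ between pools. An effect of PC2 stays open and was not tested.

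The third pattern is that most immediate-early and cytokine genes were lower in PC2 than in Luc libraries. If macrophages and neutrophils as a whole made the cytokine RNA, fewer of them would lower their markers by about the -0.80 of the cytokine list. The lower of both lists' medians was 0.033, with member SDs of 0.44 and 0.227, and macrophage members ran from -0.747 to 1.248. The lists do not separate cells that made cytokine RNA from others of their type. A loss of those cells alone therefore stays open. Shorter handling before the RNA was preserved could lower immediate-early genes, 11 of which fell, and cannot be told apart from a lower level in the living joint. For the 12 cytokine list members outside the rapid primary response, shorter handling predicts little change, yet their median was -0.59, and 8 fell and 0 rose. The 12 rapid members had a lower median of -0.97, with 7 lower and 2 higher, which shorter handling also predicts, so handling is argued against only as the whole cause. An effect of PC2 stays open and was not tested.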
